A study of Homo sapiens with 6 samples.

How the data were processed

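Gene expression was measured by RNA sequencing of 6 libraries of cells labelled as the human melanoma line SK-MEL-2, 3 given DMSO and 3 given 10 µM regorafenib for 24 h. Per the labels' protocols, messenger RNA was purified from total RNA on poly-T beads and the libraries were amplified by PCR. The submitters' processing notes name the aligner HISAT2 version 2.0.5. They also name the build mm10, which is a mouse genome. The deposited tables hold human Ensembl identifiers, and the coordinates of all 58735 genes equal those of GENCODE release 29 on GRCh38, so positions are given in GRCh38. The counting program and its strand setting are not given in the sources used here. Reads of genes that overlap on opposite strands, and of genes with close copies such as ribosomal protein, ferritin and metallothionein genes, can therefore be shared between genes.

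The authors deposited a table of whole-number read counts per gene and a table of FPKM values per gene for the same genes and libraries. Columns were tied to samples through the sample descriptions, and 0 columns of per-sample values were left unused. The deposited FPKM values equal FPKM computed from the deposited counts and gene lengths times a constant per library, between 0.9591 and 1.06. They therefore carry the same information as the counts with another scaling. Count totals ran from 15662941 to 16684999 per library, and 26293 genes had 0 counts in every library. Where a gene is said to have 0 counts, a floor of up to 3 counts is allowed for. No floor entered the CPM means or the fold changes. PCR reads without molecular identifiers are not independent molecules, so such floors cover counting error only.

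Regorafenib was compared with DMSO on the counts as deposited with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and the quasi-likelihood test was fitted with robust dispersion estimates and group as its only term. P-values were adjusted by Benjamini-Hochberg over all 15441 genes tested, with a threshold of 0.05 and, for counts of larger changes, a size limit of 2-fold. The common biological coefficient of variation was 10.2%. Fold changes are regorafenib over DMSO, CPM values are counts per 1000000 of the library total times its TMM factor, and means are given with the SD of 3 libraries. Log2 fold changes are given with an approximate standard error, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

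Lists of genes for pathways, melanoma states and other cell types, 39 in all with 954 symbols, were written before the data were examined. Of these symbols, 903 matched by the symbol in the tables, 48 through another symbol of the same identifier, 1 repeated a gene already in its list, and 2 histone symbols did not match. The 37 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Members called come from the edgeR fit and were also adjusted over the list alone. Shares of counts per library were compared with exact two-sided permutation tests, which cannot go below p = 0.1 here.

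The rule for named genes was fixed before the data were examined. It takes the 10 highest and 10 lowest log2 fold changes among called protein-coding genes with a mean log2 CPM of at least 2 and groups that do not overlap, and the 6 called genes with the smallest p-values beyond those. It adds up to 4 called members per list with the largest change and a mean log2 CPM of at least 1, or the 2 most abundant members where fewer than 2 were called. It also takes all measured target kinases of regorafenib and the 5 most abundant genes. Tested genes named outside the rule are marked in the text as picked after their values were seen. Some untested markers of the melanocyte lineage are also named outside the rule. Some genes that the rule takes are not reported here.

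Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited FPKM plus 1 or 0.1, relative log expression, upper-quartile and total-count scaling, no filter, a filter of 1 CPM in 3 libraries, protein-coding genes alone, a test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. The gene tests were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. Trend corrections for exon length, GC content and abundance used loess with a span of 0.3. Exon length was the deposited gene length, which need not equal that of any transcript. GC content was that of the longest annotated transcript of each gene. Bootstrap SEs of list medians were drawn over member genes, so they hold no spread between libraries. The trend correction and the test of 3' UTR motifs were tested on simulated values for 15441 genes, where 3% of 100 null draws of the motif test had p under 0.05. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.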

Results

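The series asked how regorafenib changes gene expression in melanoma cells. Regorafenib is an oral inhibitor of several kinases, among them VEGF receptors, PDGF receptors, KIT, RET, FGFR1 and BRAF. SK-MEL-2, the line named in the labels, is an established human melanoma line with an activated NRAS gene. Messenger RNA was sequenced from 3 libraries of cells given 10 µM regorafenib for 24 h and from 3 libraries of cells given the solvent DMSO. The deposited gene counts summed to 16684999, 15662941 and 16043295 in DMSO replicates 1 to 3, and to 15866008, 16172181 and 15876767 in regorafenib replicates 1 to 3. The tables list 58735 genes, of which 15441 had enough counts to be tested.

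Cells given regorafenib had almost no transcripts of the immediate early gene EGR1, less of other genes induced through ERK signalling, of cholesterol and fatty acid synthesis genes and of DNA replication genes, and more of interferon response, antigen presentation and NRF2 target genes. These shifts of gene groups were called by camera with a preset correlation between genes, and none was called with the correlation estimated from these libraries. EGR1, a zinc finger transcription factor induced within minutes by growth factors, went from 1183 ± 708 CPM (counts scaled to a common library total; SD, n = 3) in DMSO to 0.976 ± 0.370 with regorafenib, a log2 fold change of -10.23 ± 0.81 (SE). ESM1, which encodes a secreted proteoglycan of endothelium, went from 792 ± 134 to 13.4 ± 0.452 CPM. In the other direction, OAS2, an interferon-induced sensor of double-stranded RNA, went from 12.2 ± 1.32 to 153 ± 5.62 CPM. ABCC3, a pump that exports conjugated organic anions, went from 4.71 ± 0.141 to 103 ± 2.76 CPM.

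In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8031 genes passed an adjusted p of 0.05, which is 52.0% of those tested. Of these, 4098 were raised and 3933 lowered with regorafenib. At least a 2-fold change was found for 2215 genes, 1517 raised and 698 lowered, but for 772 on log2(FPKM + 1) and 815 on that scale with an FPKM filter. The groups did not overlap for 60.6% of the genes tested, where chance gives 10% with 3 libraries against 3. Scaling by the upper quartile put 61.1% of the calls on the raised side, against 51.0% with TMM scaling, and moved the median log2 fold change of all genes from 0.01 to 0.11. Lowered genes were the larger group with DESeq2 (3706 raised, 3864 lowered), under relative log expression scaling (3990 and 4037), on log2(FPKM + 1) (3833 and 3927), on log2(FPKM + 0.1) (3824 and 3928) and on log2(FPKM + 1) with an FPKM filter (2989 and 3706). Which direction holds more genes therefore depends on the method.

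**Figure D1:**
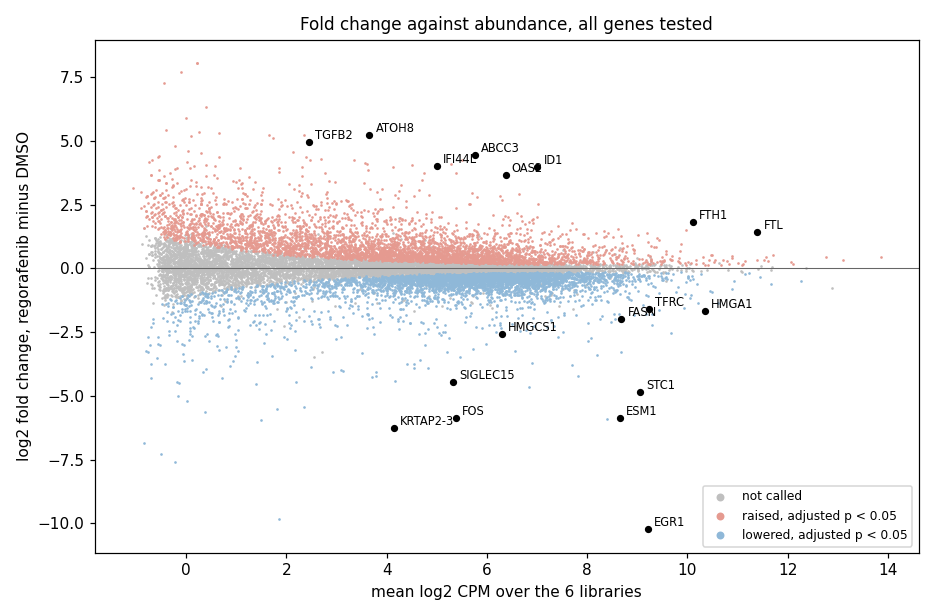
Log2 fold change (regorafenib minus DMSO) of each of the 15441 genes tested against its mean log2 CPM over the 6 libraries. Red and blue points are the 4098 raised and 3933 lowered genes, grey points were not called, and black points are named genes; EGR1 has the lowest value among the labelled genes, -10.23.

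Among protein-coding genes of at least moderate abundance, those that fell furthest besides EGR1 and ESM1 included KRTAP2-3, STC1 and SIGLEC15. KRTAP2-3, which encodes a keratin-associated protein, changed by -6.26 ± 0.21 on the log2 scale. STC1, the secreted glycoprotein stanniocalcin 1, went from 1032 ± 295 to 36.1 ± 3.61 CPM. SIGLEC15, a sialic acid-binding receptor, had a log2 fold change of -4.45 ± 0.10 and an adjusted p of 1.88e-11 in edgeR. HMGA1, a chromatin architectural protein, went from 1985 ± 18.8 to 623 ± 6.25 CPM. The steepest rises included ATOH8 (log2 fold change 5.23 ± 0.24), a helix-loop-helix transcription factor, and TGFB2 (4.97 ± 0.28), a ligand of the TGF-beta family. Without DMSO replicate 3 the value for ATOH8 was 5.82. HSPG2, the basement membrane proteoglycan perlecan, rose from 4.52 ± 0.537 to 85.3 ± 11.1 CPM. BST2 rose from 0.244 ± 0.321 to 9.67 ± 1.08 CPM. Its log2 fold change was 5.21 with all libraries and 7.05 without DMSO replicate 1.

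In GRCh38 coordinates, EGR1 (ENSG00000120738) lies on chromosome 5 from 138465490 to 138469315, ESM1 (ENSG00000164283) on chromosome 5 from 54977864 to 55022671, OAS2 (ENSG00000111335) on chromosome 12 from 112978395 to 113011723 and ABCC3 (ENSG00000108846) on chromosome 17 from 50634777 to 50692252.

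Genes were grouped by 37 lists of at least 5 measured members, and the set test camera with its preset correlation of 0.01 called 19 of them, 10 up and 9 down. With the correlation between genes estimated from these libraries, camera called 0. The smallest adjusted p was then 0.0659, and 7 lists had an unadjusted p under 0.05. The set test fry, which asks whether a list's genes move one way and does not compare them with other genes, called 29. With the preset correlation, camera's adjusted p for the called lists ran from 3.64e-15 (interferon response) to 0.0304 (TGF-beta targets among them). Camera p-values below are with the preset correlation unless an estimated correlation is named. P-values of these different kinds cannot be ranked against each other.

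Transcripts induced through ERK signalling fell. Of 32 members of that list, 29 were lowered and 2 raised, also when adjusted over the list alone, with a median log2 fold change of -1.76 and an adjusted p = 0.222 in camera with an estimated correlation. FOS, a partner in the AP-1 transcription factor, went from 82.2 ± 30.9 to 1.41 ± 0.441 CPM. DUSP6, the phosphatase that removes phosphate from ERK, and SPRY4, a feedback inhibitor of receptor signalling, were picked after their values were seen. They had log2 fold changes of -3.15 ± 0.12 and -2.86 ± 0.34. The raised members, picked in the same way, were SPRY1 (0.68), another feedback inhibitor, and KCNN4 (0.54), a potassium channel. Without DMSO replicate 2, in which EGR1 stood at 1999 CPM against 721 in DMSO replicate 1, the log2 fold change of EGR1 was -9.63.

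Inflammatory targets of NF-kB were lower in the same libraries, with a larger spread. Of 24 members, 12 were lowered and 0 raised, also when adjusted over the list alone, with a median of -2.76 and an adjusted p = 0.527 with an estimated correlation. DMSO replicate 2 held more of these transcripts than the other DMSO libraries, and without it 21 members were lowered and 2 raised. CXCL8, the neutrophil chemokine interleukin 8, averaged 667 ± 768 CPM in DMSO and 11.1 ± 2.27 with regorafenib, and its log2 fold change was -5.90 with all libraries and -4.34 without DMSO replicate 2. Its call was lost without regorafenib replicate 1, 2 or 3 (edgeR adjusted p = 0.0704, 0.0739 and 0.0726), with limma-voom and with the replicate block, within a range from 1.09e-21 to 0.0739 over its alternatives. CXCL1 and CXCL2 also lost theirs without any 1 of the regorafenib libraries and with the block, at adjusted p of up to 0.0754 and 0.0989, the highest over their alternatives, the lowest being 4.86e-23 and 9.12e-21. Their log2 fold changes were -4.20 and -4.65 with all libraries and -3.06 and -3.18 without DMSO replicate 2. IL11, a cytokine of the interleukin 6 family, had a log2 fold change of -4.45 with all libraries and -3.79 without DMSO replicate 2.

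Genes of lipid synthesis fell. Of 24 genes of the cholesterol list under SREBP2, 21 were lowered and 0 raised (median -1.14; adjusted p = 0.0839 with an estimated correlation). HMGCS1, which makes the precursor HMG-CoA, went from 135 ± 46.7 to 22.5 ± 0.217 CPM. Of 15 genes of fatty acid synthesis, 12 were lowered and 2 raised (median -0.56; adjusted p = 0.0923 with an estimated correlation). FASN, fatty acid synthase, had a log2 fold change of -1.98 ± 0.08 and SCD, the desaturase that makes monounsaturated fatty acids, -1.80 ± 0.07. The raised genes, picked after their values were seen, were ME1 (0.68), which makes NADPH, and ACSS2 (0.50), which makes acetyl-CoA from acetate. Counts for both lists were the same when adjusted over the list alone.

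Genes of cell division and ribosome assembly also fell. In the list for G1/S and DNA replication, 38 of 40 members were lowered and 0 raised, with a median of -0.76 and an adjusted p = 0.416 with an estimated correlation. CCNE2, a cyclin of the G1/S transition, had a log2 fold change of -1.82 ± 0.31 and MCM10, a replication initiation factor, -1.47 ± 0.17. The G2/M and mitosis list had 24 of 44 members lowered and 3 raised, a median of -0.22 and an adjusted p = 0.416 with an estimated correlation. MKI67, the Ki-67 antigen, went from 273 ± 38.2 to 171 ± 20.5 CPM, whereas the mitotic phosphatase CDC25B rose from 197 ± 9.23 to 362 ± 4.98 CPM. Of 34 ribosome biogenesis factors, 31 were lowered and 0 raised (median -0.62; adjusted p = 0.240 with an estimated correlation), among them BOP1 (-0.93 ± 0.07) and PNO1 (-1.19 ± 0.10). In these 3 lists, too, the counts were the same when adjusted over the list alone.

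Unfolded protein response genes of the endoplasmic reticulum fell, and cytosolic heat shock genes went both ways, with more lowered than raised. Of 23 targets of ATF6 and XBP1 in the unfolded protein response, 17 were lowered and 0 raised (median -0.42; adjusted p = 0.0923 with an estimated correlation). HSP90B1, the reticulum's HSP90, went from 1820 ± 205 to 979 ± 76.0 CPM. Of 17 cytosolic heat shock genes, 9 were lowered and 4 raised (median -0.42; adjusted p = 0.564 with an estimated correlation), and counts adjusted over the list alone were equal for both lists. HSPA8 went from 1319 ± 157 to 663 ± 71.4 CPM, and the collagen chaperone SERPINH1 rose from 195 ± 7.19 to 466 ± 15.9 CPM.

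Interferon response genes rose. Of 28 members, 27 were raised and 0 lowered, with a median log2 fold change of 1.80 and an adjusted p = 0.0661 with an estimated correlation. IFI44L went from 3.71 ± 0.908 to 59.9 ± 2.88 CPM, and OAS1, a synthetase that activates RNase L, from 4.32 ± 0.327 to 47.5 ± 1.75 CPM. Of 15 antigen presentation genes, 13 were raised and 0 lowered (median 1.07; adjusted p = 0.236 with an estimated correlation). NLRC5, the transactivator of MHC class I genes, had a log2 fold change of 1.34 ± 0.10. TAP1, a peptide transporter, had 1.75 ± 0.09, and PSMB9, an immunoproteasome subunit, 2.31 ± 0.13. The annotated spans of TAP1 and PSMB9 overlap on opposite strands, so reads may be shared between them. Counts for both lists were equal when adjusted over the list alone.

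Genes of the antioxidant factor NRF2 rose, with 20 of 23 members raised and 0 lowered, also when adjusted over the list alone (median 0.68; adjusted p = 0.0659 with an estimated correlation). Besides ABCC3, FTH1 and FTL, the ferritin subunits that store iron, rose from 492 ± 26.5 to 1727 ± 114 CPM and from 1477 ± 16.1 to 3922 ± 125 CPM. TFRC, the transferrin receptor that imports iron, fell from 905 ± 52.0 to 301 ± 28.7 CPM. Metallothionein and zinc transport genes had 4 of 7 members raised and 1 lowered (median 0.87; adjusted p = 0.244 with an estimated correlation), with MT1X at 3.84 ± 0.931 CPM in DMSO and 25.1 ± 0.369 with regorafenib. Ferritins and metallothioneins have close copies in the genome, and their counts are uncertain to that extent.

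Matrix, TGF-beta and lysosomal lists rose on balance, with members on both sides. Of 33 extracellular matrix and adhesion genes, 20 were raised and 6 lowered, and 22 and 6 when adjusted over the list alone (median 0.41; adjusted p = 0.527 with an estimated correlation). COL5A1, a chain of collagen V, went from 4.36 ± 1.03 to 73.1 ± 6.30 CPM and LOX, which crosslinks collagen, from 38.0 ± 4.18 to 219 ± 7.89 CPM. Of 19 TGF-beta family targets, 11 were raised and 5 lowered (median 0.45; adjusted p = 0.240 with an estimated correlation). The raised members with the steepest change were TGFB2, SMAD6, ID1 and ID2. SMAD6, an inhibitor of BMP signalling, had a log2 fold change of 4.27 ± 0.22. ID1, a helix-loop-helix protein induced by BMPs, went from 15.1 ± 4.40 to 241 ± 4.62 CPM, while CTGF, a matricellular protein, fell from 426 ± 79.0 to 95.7 ± 4.58 CPM. Of 39 lysosome and autophagy genes, 19 were raised and 3 lowered, and 19 and 4 when adjusted over the list alone (median 0.35; adjusted p = 0.416 with an estimated correlation). The protease CTSD had a log2 fold change of 1.81 ± 0.08 and TFEB, a transcription factor of lysosomal genes, 1.29 ± 0.20. Without DMSO replicate 2, 6 members of the lysosome list were lowered.

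Targets of ATF4 in the integrated stress response went both ways, with 12 of 36 raised and 5 lowered, also when adjusted over the list alone (median 0.22; adjusted p = 0.788 with an estimated correlation). PHGDH, which opens serine synthesis, rose from 189 ± 27.4 to 492 ± 1.52 CPM and PCK2, a mitochondrial carboxykinase, from 93.4 ± 27.3 to 321 ± 8.19 CPM. Without DMSO replicate 2, 23 members were raised and 8 lowered. Camera's call for this list was lost without DMSO replicate 1 (adjusted p = 0.106) and without DMSO replicate 3 (adjusted p = 0.0758), and fry did not call it (adjusted p = 0.0817), within a range from 7.77e-06 to 0.788 over its alternatives.

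Ribosomal protein transcripts and messenger transcripts of the mitochondrial genome rose on balance, by small amounts. Of 57 cytosolic ribosomal protein genes, 32 were raised and 0 lowered, and 34 and 0 when adjusted over the list alone (median 0.17; adjusted p = 0.527 with an estimated correlation); none was lowered under total-count, relative log expression or upper-quartile scaling either, where 45, 30 and 45 were raised, and 1 was lowered without DMSO replicate 2. RPL12 went from 789 ± 35.0 to 1032 ± 12.1 CPM. These genes took 4.12 ± 0.157% of all counts in DMSO and 4.90 ± 0.0809% with regorafenib. Of the 13 messenger transcripts of the mitochondrial genome, 10 were raised and 0 lowered, and 11 and 0 when adjusted over the list alone (median 0.45; adjusted p = 0.315 with an estimated correlation). Their share of counts was 3.87 ± 0.0528% in DMSO and 5.22 ± 0.226% with regorafenib. MT-RNR2, a mitochondrial ribosomal RNA, averaged 9493 ± 3044 and 5567 ± 182 CPM and did not pass with all libraries (edgeR adjusted p = 0.0635). It passed with DESeq2 (adjusted p = 0.00984), on the FPKM scales, without DMSO replicate 2, its highest library (log2 fold change -0.49, adjusted p = 3.2e-09), and without DMSO replicate 3 (adjusted p = 0.0442), within a range from 3.2e-09 to 0.166 over its alternatives. Genes with at least 1 count numbered 23786 ± 428 in DMSO libraries and 24853 ± 664 in regorafenib libraries. The 10 most abundant genes took 6.05 ± 0.314% and 6.88 ± 0.271% of counts, and protein-coding genes 97.1 ± 0.354% and 97.4 ± 0.0389%. That last difference, 0.274 percentage points, was -0.224 with mitochondrial transcripts left out of the total and 0.0706 without DMSO replicate 2. Each of these 5 measures gave p = 0.1 in an exact two-sided permutation test, also after adjustment over the 5, which is the smallest p that 3 libraries against 3 allow.

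**Figure D2:**
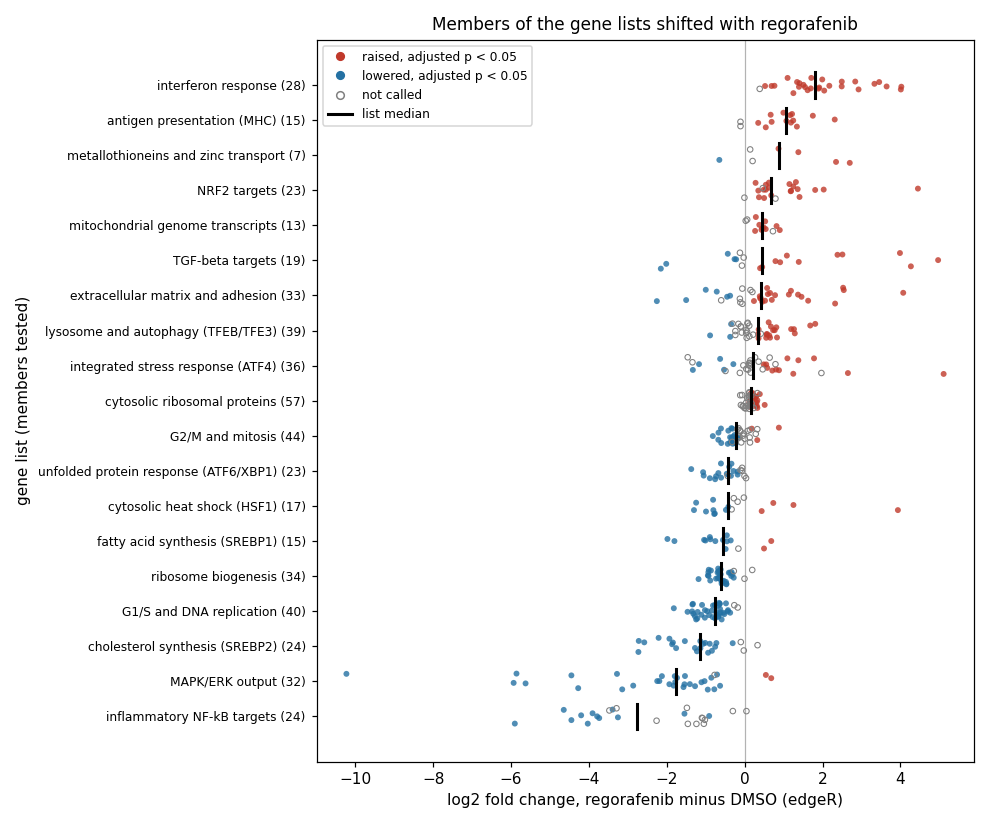
Log2 fold change (regorafenib minus DMSO, edgeR) of each tested member of the 19 lists that camera called with its preset correlation, with the number of members in parentheses. Filled red and blue points passed an adjusted p of 0.05, open points did not, and black bars are list medians, from -2.76 for inflammatory NF-kB targets to 1.80 for the interferon response. No list was called with an estimated correlation between members, which ran from -0.15 for metallothioneins and zinc transport to 0.94 for NF-kB targets.

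Kinases that regorafenib inhibits were themselves measured for 9 genes, of which 2 were raised and 5 lowered, also when adjusted over the list alone; camera did not call the list (adjusted p = 0.316). EPHA2 went from 608 ± 59.6 to 282 ± 13.5 CPM and BRAF from 28.5 ± 6.59 to 21.2 ± 1.46 CPM. The BRAF call was lost without DMSO replicate 2 (edgeR adjusted p = 0.0683), without regorafenib replicate 1 (0.0759) and without regorafenib replicate 2 (0.110), under upper-quartile scaling and on the FPKM scales, within a range from 0.00085 to 0.162 over its alternatives. The calls of KDR, a lowered gene, and DDR2, a raised one, were also lost under some alternatives, such as without regorafenib replicate 3 (edgeR adjusted p = 0.0824 and 0.0616). FGFR1 stood at 188 ± 5.16 and 177 ± 4.25 CPM and did not pass (edgeR adjusted p = 0.277). PDGFRB was raised from a mean of 0.428 to 1.97 CPM and PDGFRA lowered from 1.25 to 0.345 CPM.

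**Figure D3:**
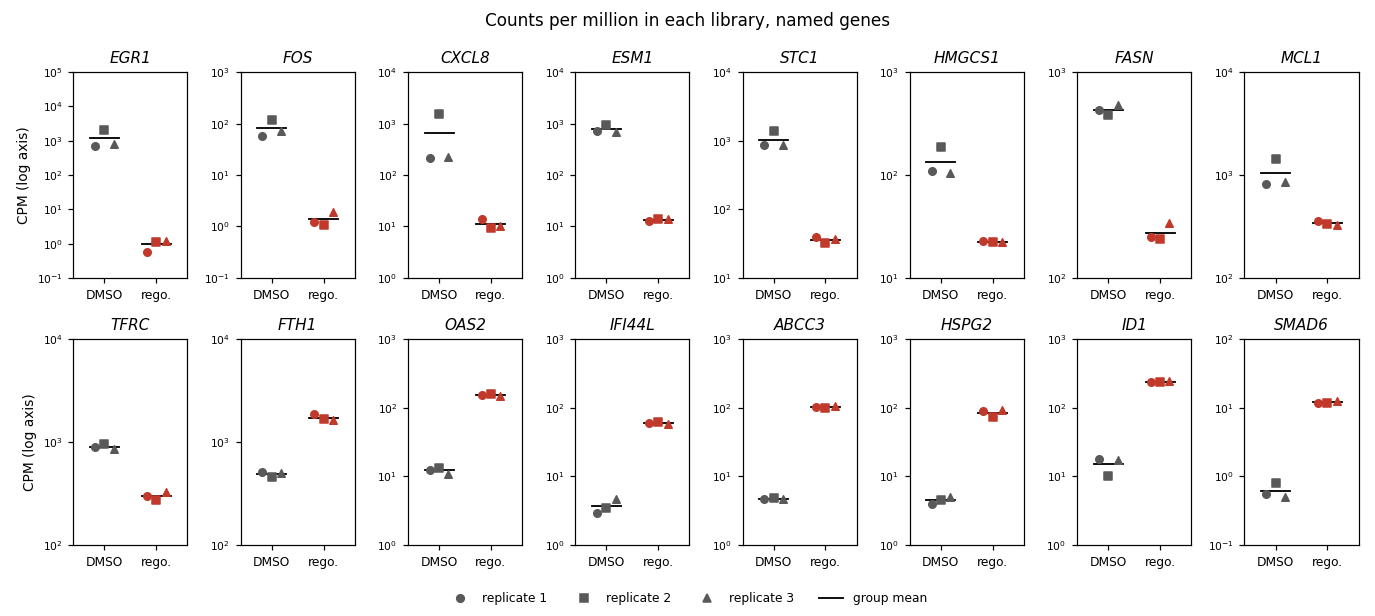
CPM per library on a log axis for 16 named genes in DMSO (grey) and regorafenib (red, marked rego.); circles, squares and triangles are replicates 1, 2 and 3, and bars are group means. EGR1 fell from a mean of 1183 to 0.976 CPM and ABCC3 rose from 4.71 to 103 CPM, and CXCL8 was higher in DMSO replicate 2 than in the other DMSO libraries.

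Several markers of the melanocyte lineage were scarce in both groups. Of 28 genes on that list, 13 had too few counts to be tested, and those 13 summed to between 16 and 37 counts per library. Some of the 13 are named here outside the rule for named genes. TYR, tyrosinase, had 1 count over all libraries, and PAX3 and S100B had 0, which allows up to 3 counts each. SOX10 had at most 8 in a library. The highest sums over all libraries among the 13 were 43 for DCT and 41 for GPR143. Camera did not call the list (adjusted p = 0.356), with 4 members raised and 6 lowered of 15 tested, 4 and 7 when adjusted over the list alone. TYRP1, a pigment enzyme, stood at 6.95 ± 4.23 and 1.46 ± 0.353 CPM, with a log2 fold change of -2.23 with all libraries and -1.63 without DMSO replicate 2, and GPNMB, a glycoprotein of melanosomes and lysosomes, rose from 41.4 ± 2.30 to 133 ± 6.82 CPM. Leukocyte markers had 0 of 15 genes with enough counts to be tested. Among 8 tested endothelial markers, 5 were lowered and 1 raised, also when adjusted over the list alone. Camera did not call this list (adjusted p = 0.202, 0.527 with an estimated correlation), and fry did (adjusted p = 0.0055). CDH5, VE-cadherin, went from 205 ± 23.1 to 82.1 ± 5.36 CPM and TIE1, an endothelial receptor kinase, from 281 ± 15.7 to 197 ± 2.01 CPM. These were the most abundant of the list. The raised member EGFL7, a secreted protein of vessels, went from 21.6 ± 2.25 to 28.6 ± 2.09 CPM, while the adhesion protein ESAM stood at 4.65 ± 0.914 CPM and the VEGF receptor KDR at 2.37 ± 0.240 CPM in DMSO. A further 4 of its 12 genes had too few counts to be tested and summed to between 1 and 17 counts per library. Of 7 tested fibroblast markers, 3 were raised and 2 lowered, and 4 and 2 when adjusted over the list alone (camera adjusted p = 0.373, 0.555 with an estimated correlation; fry called the list at 0.0014). The fibroblast list shares 3 genes with the matrix list. COL1A1, a chain of collagen I on both lists, went from 2.15 ± 0.306 to 12.6 ± 1.47 CPM and FBLN1, a matrix glycoprotein, from 55.5 ± 1.13 to 119 ± 3.02 CPM, while PDPN, podoplanin, fell from 173 ± 3.07 to 60.0 ± 4.03 CPM. The 7 untested members summed to 6, 8 and 8 counts in DMSO and to 28, 20 and 28 with regorafenib.

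The scarcity of 13 of the 28 melanocyte markers in all 6 libraries leaves the identity of these cells in question. Those 13 are the members with too few counts to be tested. Of 24 markers of dedifferentiated melanoma, 22 had enough counts to be tested. The scarcity therefore cannot tell a dedifferentiated state of the named line from another line. Levels of most of the 15 tested markers are not reported here. The endothelial list, with members at high and at low levels, does not settle that identity. That identity rests on the labels and was not tested here, so every value above holds for the cells sequenced, whichever line they are. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which can be technical. In simulated counts of 14691 genes for this comparison, the test recovered 56.5% of 1.5-fold, 80.3% of 2-fold and 98.4% of 4-fold changes, and 6.37% of 157 calls were false. The simulation changed 200 genes, far fewer than were called in the data, so these shares need not hold for the data.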

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

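Counts of list members without DMSO replicate 2, under total-count scaling and with the block were added after the data were seen; all other alternatives were planned. Under total-count scaling, raised members of the G2/M list became 5 in place of 3 and of the cholesterol list 1 in place of 0, and lowered members became 3 in place of 6 for PI3K and FOXO targets, 2 in place of 5 for the hypoxia response and 0 in place of 2 for nuclear oxidative phosphorylation. With the block, raised members of the ERK list became 1 in place of 2 and lowered members of the oxidative phosphorylation list 1 in place of 2. Raised genes were the larger group with all libraries, and lowered genes were with DESeq2, relative log expression scaling and the FPKM scales. No named gene reversed its direction under the alternatives run, and every gene called both with all libraries and under a given alternative kept its direction. The count of changed genes, 8031, was 7570 with DESeq2, 8067 with limma-voom, 8442 with no filter and 6779 to 8868 with each library left out in turn, where raised genes ran from 3467 to 4458 and lowered genes from 3312 to 4410. The count of genes changed at least 2-fold, 2215, ran from 2095 to 2452 with a library left out, but was 772 on log2(FPKM + 1) and 815 on that scale with an FPKM filter. A pseudocount of 1 shrinks the fold changes of low genes by construction, and with 0.1 in its place 1881 genes passed.

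The 19 lists called by camera became 0 with an estimated correlation and 29 with fry; leaving out a library gave 18 to 20. The TGF-beta list had an adjusted p of 0.0533 with the replicate block, in a range from 2.81e-05 to 0.240. With the replicate number as a block, 7722 genes were called and 7593 of these were among the 8031. TNC, CXCL1, CXCL2 and CXCL8 were not called in that fit. Deviations of equal-numbered libraries from their group means correlated at -0.136, -0.00568 and 0.0618 across genes. DMSO replicate 1 correlated best with regorafenib replicate 3 (0.0975), and the highest value was for DMSO replicate 2 with regorafenib replicate 1 (0.128). These low values show no pairing by number but cannot exclude one, and the labels name none.

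Of 160 named genes, 13 lost their call under at least 1 alternative and 1, MT-RNR2, gained one. The difference in the share of counts of protein-coding genes, 0.274 percentage points, was -0.224 with mitochondrial transcripts left out of the total, and 0.0706 without DMSO replicate 2. In summed FPKM it was 0.685, and the differences for mitochondrial messenger transcripts and the 10 most abundant genes were 3.82 and 2.92 points in place of 1.35 and 0.829. FPKM weights short transcripts more by construction. At the depth of these libraries, changes of 1.5-fold were recovered for 56.5% of genes so changed in a simulation with 200 changed genes. That share need not hold for the data, where far more were called, but genes not called can still have changed.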

Other observations

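The tests of leukocyte transcripts were chosen after the counts they use had been seen; the other tests were written before their values were known, on patterns picked from the data.

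Of 16 BCL2 family genes, 3 were raised and 4 lowered, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.711). MCL1, a survival factor with a short-lived transcript, went from 1039 ± 350 (SD, n = 3) to 339 ± 13.6 CPM and BCL2A1, another survival factor, from 26.1 ± 14.1 to 1.39 ± 0.268 CPM, while BMF, which promotes death, went from 2.26 ± 0.757 to 13.3 ± 0.603 CPM. Of 26 p53 targets, 9 were raised and 7 lowered (camera adjusted p = 0.949); CDKN1A, the inhibitor p21, went from 126 ± 47.5 to 28.5 ± 3.14 CPM and TP53INP1 from 1.80 ± 1.02 to 5.58 ± 0.537 CPM. Targets of YAP and TEAD split evenly, with 10 of 22 raised and 10 lowered (camera adjusted p = 0.871), and F3, tissue factor, had a log2 fold change of -2.22 ± 0.16. In the p53 and YAP lists, which were not called, the signs of median (0.06 and 0.05), mean (-0.13 and 0.04) and test (up and down) differ.

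Growth factor genes also changed level, in both directions. HBEGF, a ligand of the EGF receptor, went from 171 ± 81.7 to 17.8 ± 0.631 CPM and FGF1 from 26.0 ± 2.93 to 1.55 ± 0.409 CPM. NRG1, another ligand, rose from 4.06 ± 1.17 to 8.47 ± 0.895 CPM. They belong to a list of 20 receptor kinase and ligand genes with 10 raised and 10 lowered (camera adjusted p = 0.898). That list's median and mean were -0.03 and -0.16 while the test pointed up. Of 24 glycolysis genes, 3 were raised and 9 lowered (camera adjusted p = 0.179), with PFKFB3, which makes the activator of phosphofructokinase, at a log2 fold change of -1.16 ± 0.07. Of 56 nuclear genes of oxidative phosphorylation, 14 were raised and 2 lowered, 14 and 1 when adjusted over the list alone (camera adjusted p = 0.317), and 7 were lowered without DMSO replicate 2. Markers of dedifferentiated melanoma had 9 of 22 raised and 7 lowered, 10 and 7 when adjusted over the list alone (camera adjusted p = 0.949). The median of that list was -0.22 and its mean 0.07. Among its members, FOSL1, an AP-1 subunit, went from 971 ± 164 to 282 ± 4.50 CPM and NGFR, a neural crest receptor, from 0.728 ± 0.262 to 4.34 ± 1.79 CPM. Of 11 tested histone genes, 5 were lowered and 0 raised (camera adjusted p = 0.0643). The call of this list depends on the method. Camera called it under total-count scaling, on log2(FPKM + 1) and without regorafenib replicate 1, 2 or 3, and fry called it. It was not called with an estimated correlation (adjusted p = 0.307), under the strict filter of 1 CPM in 3 libraries (0.147), with the replicate block or without DMSO replicate 1, 2 or 3. After the values were seen, 7 genes known to respond to BMPs were picked out, and all were raised in edgeR: ATOH8, SMAD6, ID1, ID2, ID3 (log2 fold change 2.38), BAMBI (1.39) and SMAD7 (1.08). No test separates this choice from chance, since the genes were picked for their rise.

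DMSO replicate 2 stood apart from the other DMSO libraries in immediate early, chemokine and cytokine genes. Its counts differed from those of DMSO replicates 1 and 3 with a chi-square per degree of freedom of 22.7 and 20.8, against 3.25 between the latter. The 54 members of the ERK and NF-kB lists lay a median 0.96 log2 units above the other DMSO libraries. After correction for exon length, GC and abundance the excess was 1.01 ± 0.17 (bootstrap SE over member genes). By list, it was 1.61 ± 0.26 for NF-kB targets and 0.35 ± 0.21 for ERK-induced genes, the latter below 2 SE. The correction thus argues against such a trend as the cause for NF-kB targets and does not decide for ERK-induced genes alone. Summed counts of 10 leukocyte-restricted genes were 2 in this library and 3 and 5 in the other DMSO libraries, too few for leukocytes as a source. Of the 29 ERK-induced genes lowered with all libraries, 100% were also lowered without it, so that fall does not rest on this library. The labels name no difference between the DMSO libraries, and besides leukocytes no biological explanation was tested.

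Interferon response genes, 27 of 28 raised but not called as a list with an estimated correlation (adjusted p = 0.0661), rose in cultures that held few interferon transcripts. After correction for length, GC and abundance the list's median was 1.78 ± 0.19 (bootstrap SE over member genes), against 1.80 before. This argues against such a trend as the source. Leukocyte-restricted transcripts rose by 0.0091% of the rise of the interferon list in summed CPM, which argues against leukocytes in the treated cultures. Counts of 22 interferon genes summed to 10, 11 and 5 in regorafenib libraries and to 22, 13 and 8 in DMSO libraries. The rule set in advance took 3 or fewer counts in most regorafenib libraries as evidence against interferon transcripts. It took counts above 3 and above every DMSO library, in each regorafenib library, as evidence for them. Neither held, and the counts were no higher with regorafenib. These few counts do not decide whether interferon made at sampling takes part, and earlier interferon was not measured. A response of the cells to regorafenib remains open as a hypothesis.

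Of 57 ribosomal protein genes 32 were raised and of 34 ribosome assembly factors 31 were lowered, though neither list was called with an estimated correlation (adjusted p = 0.527 and 0.240). The ribosomal protein median was 0.23 ± 0.01 (bootstrap SE over member genes) after correction for length, GC and abundance, against 0.17 before. Before correction it was 0.16, 0.25 and 0.27 under relative log expression, total-count and upper-quartile scaling. These medians argue against library scaling and against a trend with GC or with the deposited gene length, though the SE leaves out the spread between libraries. That length was 4204 for RPS23 and 2452 for RPL12 and need not be the length of the transcript sequenced. A trend with transcript length was not tested and stays open. Reads shared with ribosomal protein pseudogenes were not examined. Messenger RNAs of ribosomal proteins begin with a 5' terminal oligopyrimidine tract, and a hypothesis was that others of that class rise too. The median of 23 such genes, 0.08, lay at the 96.0th percentile of 10000 random lists matched on abundance, whose median was -0.13. This is consistent with a shift of the class relative to other abundant transcripts, though 6 of the 23 were called raised and 2 lowered.

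Some lowered transcripts, such as those of early response genes and cytokines, belong to classes known for short half-lives, and a hypothesis was that lowered genes carry more AU-rich destabilising motifs. The nonamer WTATTTATW was found in the 3' UTR of 29.6% of 3576 lowered genes and in 22.4% of unchanged genes matched on 3' UTR length and abundance (permutation p = 0.0001, the smallest that 10000 permutations can give). Among 3516 raised genes the share was 16.1%, against 19.0% in matched unchanged genes and 17.2% with matching on 3' UTR GC content in place of abundance. With matching on 3' UTR length and 3' UTR GC content in place of abundance, 25.0% of unchanged genes had the nonamer. The share in lowered genes still exceeded this by 4.62 percentage points (permutation p = 0.0001). The matching used bins, within which AU content still varies, so it cannot exclude AU content of the 3' UTRs as the cause. A contribution of transcript stability to the pattern may follow from the excess, but half-lives were not measured and the pattern was found and tested on the same libraries.

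The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. For the 8031 genes changed, the 4098 raised, the 3933 lowered and the 2215 changed at least 2-fold, the highest count in another split was 0 genes, and 1 of the 10 splits, the real one, gave as many. For the 19 lists called by camera with its preset correlation, the highest count in another split was 17, again with 1 split as large. Each other split joins 2 libraries of a treatment with 1 of the other, so it carries part of the treatment effect, which also widens the spread within groups. The counts in other splits therefore do not measure calls made without a difference.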
